A study of Mus musculus with 6 samples.

How the data were processed

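Single-nucleus RNA sequencing (10x Genomics 3' chemistry, v3.1, on nuclear RNA) was available for retinas of wild-type C57BL/6J mice at 3 and 18 months of age, with 3 libraries per age. The deposited files hold raw UMI counts per gene and barcode, a unit checked on the values, which are whole numbers. Per the file headers, the counts came from Cell Ranger, release 7.1.0 for replicate 1 of both ages and release 7.2.0 for the other libraries. Per the labels, the genome build was mm10 and Seurat was also used by the authors, whose filters, clusters and cell type names were not used here. The lowest UMI total of a barcode was 500 to 502 in the 6 libraries, so a lower limit on UMIs had been applied before deposit. The labels give no sex, batch, day or pooling, and do not say that each library is a separate animal. The p-values therefore measure the spread between libraries, part of which may be technical. Coordinates were taken from GENCODE M21 on the same build, which holds 32235 of the 32285 gene identifiers of the files.

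Nuclei were kept with at least 300 detected genes and at most 5% of UMIs from mitochondrially encoded genes. These limits left 55230 of 62893 barcodes. The mitochondrial limit removed 41.9%, 23.8% and 9.36% of barcodes in 3-month replicates 1 to 3 and 9.16%, 2.11% and 1.12% in 18-month replicates 1 to 3. The caller of Scrublet marked at most 1 nucleus per library and was not used. Instead, the nuclei with the highest Scrublet scores were removed in each library at a rate of 0.8% per 1000 nuclei (4989 nuclei), which left 50241 nuclei. Because this rate follows the number of nuclei, 12.9% were removed from 18-month replicate 2 and 4.19% from 3-month replicate 1. All libraries were clustered together without batch integration in scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1, leidenalg 0.10.2), under Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0.

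Clusters were named from marker genes fixed before the data were examined. A cluster needed at least 3 markers, and at least 25% of its class's markers, above a log2 fold of 1 over the other clusters, and no unrelated class that also met this. A cluster stayed without a class if its 10 leading genes held more markers of an unrelated class than of its own. It also stayed without one if at least 10 of its 50 leading genes were shared with a cluster of an unrelated class that had more of its own markers among them. Clusters under 300 nuclei were first divided again at a Leiden resolution of 0.5. These numerical settings, unlike the markers, were set after looking at the clusters and before any comparison of ages. Of 56 clusters, 31 were named and 25, with 22602 nuclei, were not. The unnamed clusters with markers of several classes held 11.4% ± 7.65 of nuclei at 3 months and 20.6% ± 16.6 at 18 months (SD, n = 3 in each). Clusters with too few markers held 0.833% ± 0.884 and 20.9% ± 33.2, the latter mainly from cluster 13, which took 59.2% of 18-month replicate 3. Clusters led by genes of another class held 10.4% ± 1.39 and 5.35% ± 4.86. Cluster 6, whose leading genes were shared with another class, held 12.3% and 10.4% of the 2 libraries of release 7.1.0 and under 0.08% of each of the others.

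Counts were summed per library over the nuclei of a class, and 8 classes with at least 20 nuclei in every library were tested for genes. The test, fixed before the data were examined, was the quasi-likelihood test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3) with age as the only term, TMM normalisation, filterByExpr and a Benjamini-Hochberg adjusted p at or below 0.05. The low-count filter of edgeR left 5435 to 13628 genes per class. Normalised CPM below are library-scaled counts (CPM) with TMM factors, and plain CPM, without these factors, are used where a gene stood below the filter and where the text says so. The 22 gene lists (643 genes, 2 of them absent from the files) were also fixed beforehand and were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. Adjustment was over all lists and the 6 main classes together. The difference of the age effect between rods and Müller glia was tested as an interaction with a term per library. Shares of nuclei were compared by two-sided exact permutation tests, which cannot give a p under 0.1 with 3 against 3 libraries.

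The rule for named genes, also fixed beforehand, took the 12 largest log2 changes per direction in rods and in Müller glia and the 6 largest in each other class. It required an adjusted p at or below 0.05, a mean of at least 20 CPM, no overlap between the ages and a mean CPM of at least 20% of the highest class. It left out gene models without a proper name and sex-linked transcripts, and it added 5 fatty acid genes in each main class and up to 4 called members per list. Not every gene that the rule takes is named in the text. The fit with age alone gave no gene to name. The rule was therefore applied to a second edgeR fit with the Cell Ranger release as an additional term, which was chosen after the data had been examined and after its count of calls had been seen. The alternatives fixed beforehand were DESeq2 1.42.0, RLE size factors, no low-count filter, the replicate number as a term, each library left out, stricter limits on nuclei, doublets kept, thinned sums and Leiden resolution 0.5. Added after the data were examined were the release term, with and without each library of release 7.2.0, those 4 libraries alone, a mitochondrial limit of 15% and shares among named nuclei.

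The fits were tested on simulated data: negative binomial counts were drawn with the means, library sizes and dispersions of the real sums, and 100 genes were changed 2-fold and 100 genes 4-fold between the ages. With age alone, 4% of 2-fold and 62% of 4-fold changes were called in rods, and 6% and 67% in Müller glia. With the release term the figures were 59% and 100% in rods, where 14 of 173 calls were false, and 22% and 78% in Müller glia. The interaction test found 2% and 14%. Genes were drawn independently of each other, and rods and Müller glia without deviations shared within a library. These figures therefore need not hold for the real sums. Figures were drawn with matplotlib 3.10.9.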

Results

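The series profiled nuclear RNA of retinas from young (3-month) and old (18-month) wild-type mice, with 3 libraries per age. Its title concerns vision loss with age and supplementation with polyunsaturated fatty acids, but no supplemented animal is among these libraries. The files held 19449782, 15905689 and 20364509 UMIs for 3-month replicates 1 to 3, and 21453735, 29340705 and 21803522 UMIs for 18-month replicates 1 to 3. After filtering, 5027, 6192 and 6537 nuclei remained at 3 months and 5613, 14083 and 12789 at 18 months. The median mitochondrial share of UMIs in these nuclei was 2.52%, 2.26% and 1.52% at 3 months and between 1.08% and 1.35% in the 3 libraries at 18 months. Class names below stand for clusters that were rod-like, cone-like and so on by their markers. Summed UMIs per library ran from 157630 to 4378686 for rods, from 86417 to 725722 for Müller glia, from 111545 to 818786 for cones and from 1291033 to 3839383 for amacrine cells. They ran from 110161 to 744220 for rod bipolar cells, from 54570 to 768314 for cone bipolar cells, from 206972 to 444966 for horizontal cells and from 854990 to 6478640 for retinal ganglion cells.

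The first comparison asked whether the cellular makeup of the retina differed between the ages. Horizontal cells, the interneurons of the outer plexiform layer, made up 2.31% ± 0.11 of nuclei at 3 months and 1.0% ± 0.14 at 18 months (SD, n = 3). Microglia, the resident immune cells, made up 0.087% ± 0.030 and 0.43% ± 0.27, and pericytes or smooth muscle 0.039% ± 0.023 and 0.229% ± 0.058. In 3-month replicates 1 to 3 these were 6, 5 and 4 microglia and 2, 1 and 4 pericytes or smooth muscle. Cluster 22.2 had 11 of 12 pericyte markers but stayed unnamed, since it also had pigment epithelium markers. It held 3, 7 and 12 nuclei of 3-month replicates 1 to 3 and 6, 20 and 6 of 18-month replicates 1 to 3. Clusters 31.2 and 31.4, with 13 and 11 of 13 microglia markers, stayed unnamed for markers of other classes as well. Cluster 31.2 held 8, 3 and 16 nuclei of the 3-month replicates and 23, 31 and 0 of the 18-month replicates. Cluster 31.4 held 0, 0 and 0, and 6, 1 and 45. The closest shares of named microglia were 0.119% in 3-month replicate 1 and 0.135% in 18-month replicate 2. As shares of all nuclei, the libraries of the ages did not overlap in these 3 classes, and the direction was the same within release 7.1.0 and within release 7.2.0, where the horizontal cell share differed by -1.15 and -1.39 percentage points. As shares of the nuclei given a class, a setting chosen after the data had been examined, horizontal cells stood at 3.11%, 2.95% and 3.40% in 3-month replicates 1 to 3 and at 1.56%, 1.49% and 5.25% in 18-month replicates 1 to 3. They overlapped there, with a difference of -0.39 points (permutation p = 1), while microglia and pericytes or smooth muscle did not overlap (differences of 1.08 and 0.621 points). With the other clustering the microglia libraries overlapped, at 0 of 12789 nuclei in 18-month replicate 3 against 3 or 4 nuclei in each 3-month library. The difference fell from 0.343 to 0.165 points. Clusters 19.3 and 19.4 of that clustering, with 12 and 11 of 13 microglia markers, were unnamed for markers of other classes as well. They held 31 and 66 nuclei of 18-month replicate 3. Rods made up 24.2% ± 15.6 and 16.5% ± 14.5, with a difference of 10.1 points within release 7.1.0 and of -16.7 points within release 7.2.0. Retinal ganglion cells, the output neurons, made up 18.9% ± 8.18 and 7.98% ± 6.34, with differences of 3.49 and -18.1 points.

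No class passed the exact permutation test of shares. The p was 0.1 for horizontal cells, microglia and pericytes, which is the smallest that 3 against 3 libraries can give, and the adjusted p was at least 0.433 over 13 classes. The shares also depend on the lower UMI limit of the files, on the mitochondrial limit of 5%, which removed more barcodes at 3 months, and on nuclei without a class, which made up 26.7% ± 2.09 at 3 months and 50.3% ± 27.0 at 18 months, with 80.4% in 18-month replicate 3.

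**Figure D1:**
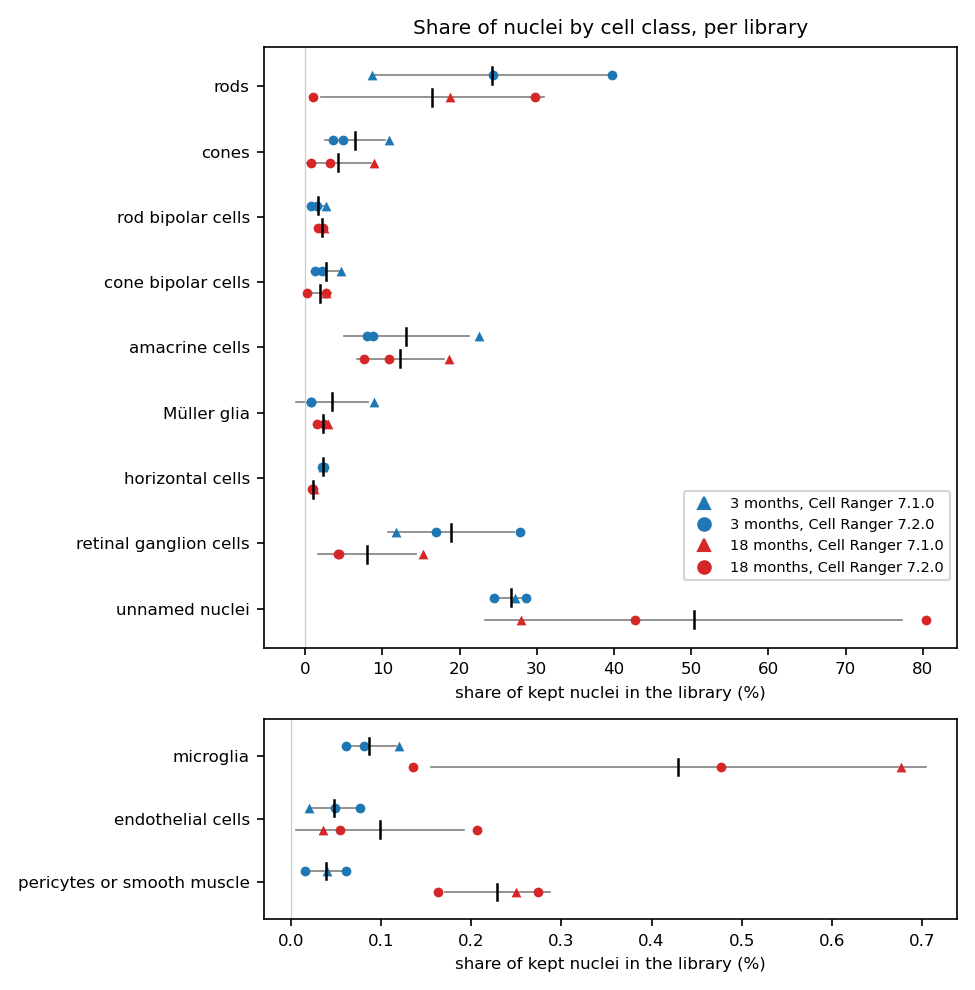
Percent of kept nuclei in each class, with 1 point per library, coloured by age and shaped by Cell Ranger release, a vertical bar for the mean and a line for the SD of 3 libraries per age. The 3-month and 18-month libraries do not overlap for horizontal cells (2.31% and 1.0% on average), microglia and pericytes or smooth muscle.

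Rods, the dim-light photoreceptors, were compared next, to ask which transcripts differ with age. With age as the only term, no gene passed in edgeR (0 of 11382, with 850 at an unadjusted p under 0.05), while DESeq2 called 11. The replicate number as a term, an alternative fixed beforehand, gave 1137 calls, but the numbers were not taken to pair the samples. With the Cell Ranger release as an additional term, a fit chosen after the data had been examined, 1124 genes passed, 340 higher and 784 lower at 18 months. The gene that rose most by the naming rule was Dpp10, an auxiliary subunit of Kv4 potassium channels (ENSMUSG00000036815, chromosome 1, 123321471 to 124045559, mm10). It went from 39.3 ± 8.92 to 381 ± 111 normalised CPM (SD, n = 3), a log2 change of 3.32 ± 0.29 (SE) with an adjusted p of 4.6e-05. Rbp3, the interphotoreceptor retinoid-binding protein (ENSMUSG00000041534, chromosome 14, 33954003 to 33964216), fell from 1790 ± 278 to 581 ± 120 normalised CPM, a log2 change of -1.62 ± 0.28 with an adjusted p of 0.011.

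Among the other genes that rose in this fit were Immp2l, a subunit of the inner mitochondrial membrane peptidase (168 ± 122 to 595 ± 70.4 normalised CPM), and Amy1, an amylase (93.1 ± 26.0 to 306 ± 26.3). Chrna7, the alpha 7 nicotinic receptor subunit, went from 10.5 ± 4.88 to 38.9 ± 0.353. The 12 named risers also included Trim43c, Dnah7c, Csrp3, Tmem116, Skap2, AC149090.1, Fndc1 and Glb1l3, with log2 changes of 1.64 to 3.06. Genes that fell included the endoplasmic reticulum chaperones Calr (281 ± 68.4 to 93.5 ± 16.3 normalised CPM) and Hspa5 (240 ± 117 to 64.7 ± 28.2). Reep6, an endoplasmic reticulum protein of rods, fell from 801 ± 371 to 256 ± 42.1. Others that fell were the serine protease Htra1, the monocarboxylate transporter Slc16a3, Tmsb15b1, Smim27, Gpsm3, Rps29 and Dync2li1, with log2 changes of -1.88 to -1.46. Of the 1124 calls, 227 met every part of the naming rule apart from its limit of 12, 90 of them higher and 137 lower.

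The count of calls in rods changed with the libraries used. With the release term, 17 genes passed without 3-month replicate 2, 9 without 3-month replicate 3, 56 without 18-month replicate 2 and 634 without 18-month replicate 3, which held 134 rods. Each of these 4 fits has 1 residual degree of freedom less, and in each every one of the 1124 calls that was tested, 1119 to 1124 of them, kept its direction. In the 4 libraries of release 7.2.0 alone 996 of the 1124 passed. In rods drawn to a like mitochondrial percent in every library (59 to 1428 rods each), 315 genes passed in that fit. Of the 1124 calls 1034 were tested there, all with the same direction, and 258 of them passed. All these fits use libraries from which the 1124 calls had been picked. A kept direction or a repeated pass therefore does not add to the calls. Of 3 rod clusters, cluster 4 held most rods of the 2 libraries of release 7.1.0 (364 at 3 months and 986 at 18 months), with at most 75 in any other library. Cluster 5 held most rods of 3-month replicate 3 (923) and of 18-month replicates 2 and 3 (3997 and 129), and 736 of 3-month replicate 2. Cluster 2 held most of 3-month replicate 2 (1729) and 663 of 3-month replicate 3. The class itself depended on the clustering: at the other resolution it held 49 and 68 rods in the libraries of release 7.1.0 instead of 433 and 1050. A cluster with 357 and 989 of their nuclei got no class there, since its leading genes were shared with rod bipolar cells. With age alone 251 genes passed in the rods of that clustering. Dpp10 stood at 482 plain CPM in rods and 425 in horizontal cells of 18-month replicate 3, and its mean in rods was 36.5% of that in retinal ganglion cells.

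**Figure D2:**
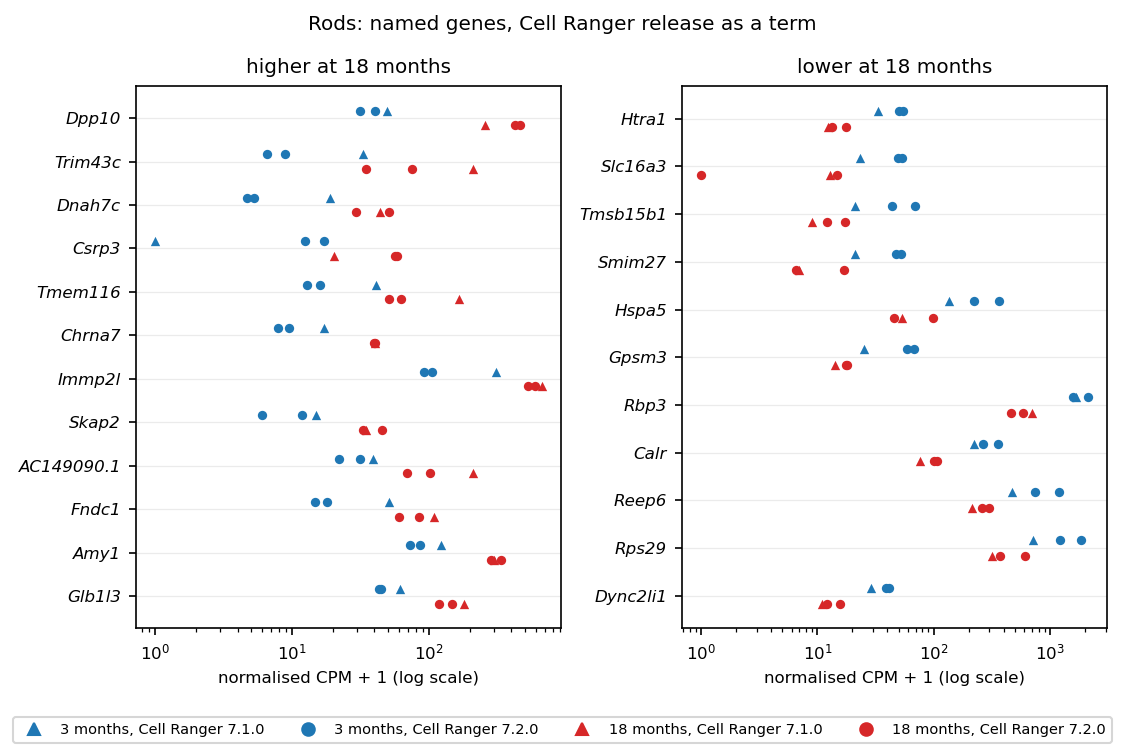
Normalised CPM plus 1 on a log axis of the rod genes that the naming rule took for their log2 change, with 1 point per library, coloured by age and shaped by Cell Ranger release. The 3-month and 18-month libraries do not overlap for any of them, and Dpp10 lies between 30.3 and 48.1 normalised CPM at 3 months and between 254 and 464 at 18 months.

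Gene groups fixed beforehand were compared in the 6 main classes, to ask which pathways moved together. In rods, 60 of 60 measured genes of the cytosolic ribosome, 74 of 74 nuclear genes of oxidative phosphorylation and 13 of 13 mitochondrially encoded genes were lower at 18 months with age as the only term. Their median log2 changes were -1.26, -1.18 and -0.85. Of the 29 rod phototransduction and disc genes 26 were lower (median -1.07), as were 21 of 25 glycolysis genes (-0.81), 28 of 34 genes of heat shock and the unfolded protein response (-0.77), 23 of 25 antioxidant and metallothionein genes (-0.71) and 19 of 23 cholesterol genes (-0.53). These 8 groups in rods passed camera, with adjusted p between 3.16e-15 for oxidative phosphorylation and 0.00243 for cholesterol synthesis and uptake, and none did with an estimated correlation (adjusted p = 0.625 for each with an estimated correlation). In rods drawn to a like mitochondrial percent the mitochondrially encoded median, -0.85 in all rods with the release term, was -0.11. The median mitochondrial share of UMIs over all nuclei was lower in every 18-month library than in any 3-month library. In rods it overlapped, at 3.52%, 2.94% and 1.66% in 3-month replicates 1 to 3 and 1.82%, 1.27% and 1.94% in 18-month replicates 1 to 3.

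Of the 2 edgeR fits, single members of these groups passed over all genes in rods with the release term alone: 52 of 60 ribosomal genes, 59 of 74 of oxidative phosphorylation, 13 of 29 of rod phototransduction, 10 of 25 of glycolysis, 12 of 34 of heat shock and the unfolded protein response, 5 of 25 antioxidant, 3 of 13 mitochondrially encoded and 2 of 23 cholesterol genes, all lower. Adjusted over the list alone, the counts in that fit were 59, 70, 17, 15, 17, 10, 12 and 0. Examples were Rps29 (1260 ± 569 to 430 ± 155 normalised CPM), Uqcrq of complex III (518 ± 346 to 172 ± 106), Cnga1, the channel subunit of rods (4000 ± 2640 to 1120 ± 304), and Gapdh (2730 ± 2250 to 930 ± 724). With age as the only term, 3 genes of heat shock and the unfolded protein response and no ribosomal or oxidative phosphorylation gene passed over the list alone.

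Over the 6 main classes, 40 of 129 pairs of list and class passed with the preset correlation, 37 lower and 3 higher. None of the 40 passed with an estimated correlation (smallest adjusted p = 0.625 with an estimated correlation). The cytosolic ribosome, oxidative phosphorylation, mitochondrially encoded and rod phototransduction lists were lower in all 6, and cone phototransduction was lower in cones, both bipolar classes and amacrine cells. Cholesterol genes were lower in rods, cones and amacrine cells, glycolysis in rods and cones, heat shock genes in rods and amacrine cells, antioxidant genes in rods and immediate-early genes in amacrine cells. The Müller glia homeostasis list was higher in amacrine (median 0.37), rod bipolar (0.40) and cone bipolar cells (0.43), and at a median of -0.22 in Müller glia themselves it did not pass (adjusted p = 0.0563). The other 11 lists passed in no class: fatty acid elongation and desaturation, peroxisomal beta-oxidation, DHA uptake and phospholipid remodelling, the ribbon synapse, the mGluR6 cascade, complement, interferon response and antigen presentation, reactive gliosis, cell cycle arrest and senescence, the circadian clock and the visual cycle. In the pairs that passed, median, mean and test had 1 sign, and they differed in sign in 10 of the 89 other pairs.

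Members of a list moved together between libraries of one age, with an estimated correlation between genes of 0.98 for the cytosolic ribosome in rods.

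**Figure D3:**
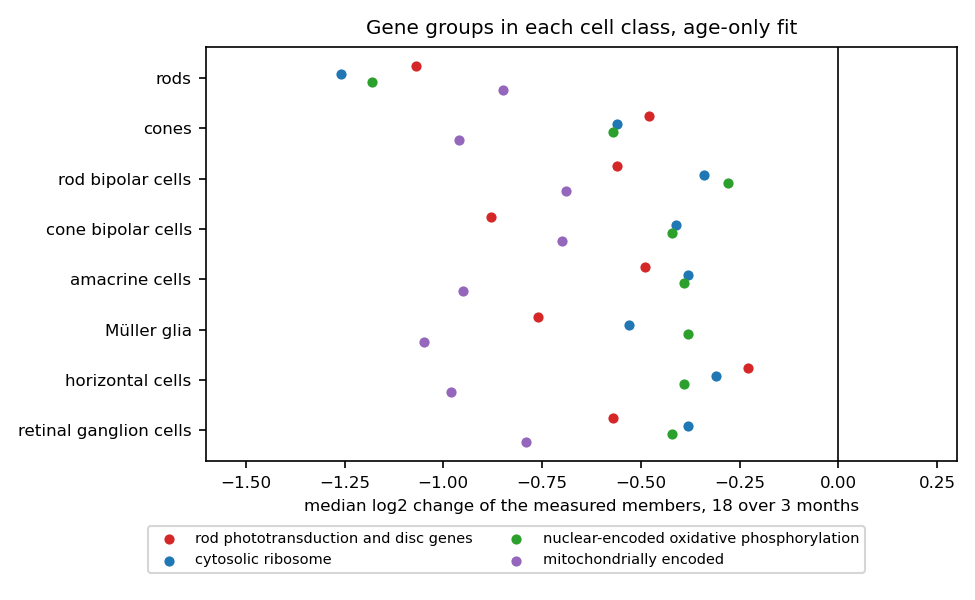
Median log2 change at 18 months against 3 months of the members of 4 gene groups in each of 8 classes, from the fit with age as the only term. The medians of all 4 groups lie below 0 in all 8 classes, from -1.26 for the cytosolic ribosome in rods.

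The enzymes that elongate and desaturate long-chain fatty acids were compared because the series concerns polyunsaturated fatty acids. Elovl4, the elongase of very-long-chain fatty acids in photoreceptors (ENSMUSG00000032262, chromosome 9, 83778692 to 83806277), stood at 688 ± 252 normalised CPM at 3 months and 359 ± 105 at 18 months in rods (SD, n = 3). Its log2 change there was -0.95 ± 0.42 (SE), with an adjusted p of 0.553 with age alone, and -0.93 ± 0.24 with an adjusted p of 0.0296 with the release term. Elovl2, which elongates polyunsaturated fatty acids on the way to docosahexaenoic acid (ENSMUSG00000021364, chromosome 13, 41182381 to 41220405), was highest in cones, at 122 ± 19.5 and 132 ± 48.7 normalised CPM. In rods Elovl2 stood at 65.0 ± 20.3 and 40.7 ± 22.9, a log2 change of -0.56 ± 0.43 with an adjusted p of 0.596. In Müller glia Elovl2 lay below the low-count filter and was not tested, at 24.7 ± 3.61 and 10.3 ± 1.77 plain CPM from 20 and 14 UMIs in all.

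Fads2, the delta-6 desaturase, was highest in Müller glia, at 88.1 ± 10.7 and 53.2 ± 27.5 normalised CPM, and Fads1 there stood at 54.4 ± 10.4 and 39.6 ± 13.1. Their log2 changes were -0.71 ± 0.42 and -0.30 ± 0.45, each with an adjusted p of 0.999. Log2 changes with age alone were -0.26 for Fads2, -0.02 for Fads1 and -0.14 for Elovl5 in rods, -0.56 for Elovl4 and -0.34 for Elovl5 in Müller glia, and -0.11 for Elovl4 and 0.41 for Elovl5 in cones. They were -0.03 and -0.20 for Elovl4 in rod and cone bipolar cells, and 0.08, -0.02, 0.34, -0.12 and -0.23 for Elovl2, Elovl4, Elovl5, Fads1 and Fads2 in amacrine cells. None of these passed, and Fads1 and Fads2 in cones and all but Elovl4 in both bipolar classes lay below the low-count filter. In rods 9 of 12 measured genes of the list were lower and 3 higher (median -0.26, adjusted p = 0.304). Elovl4 and Tecr, the trans-2-enoyl-CoA reductase of the elongation cycle (337 ± 178 to 170 ± 41.4 normalised CPM, adjusted p = 0.049), passed with the release term, also when adjusted over the list alone, while with age alone 0 passed over the list alone.

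**Figure D4:**
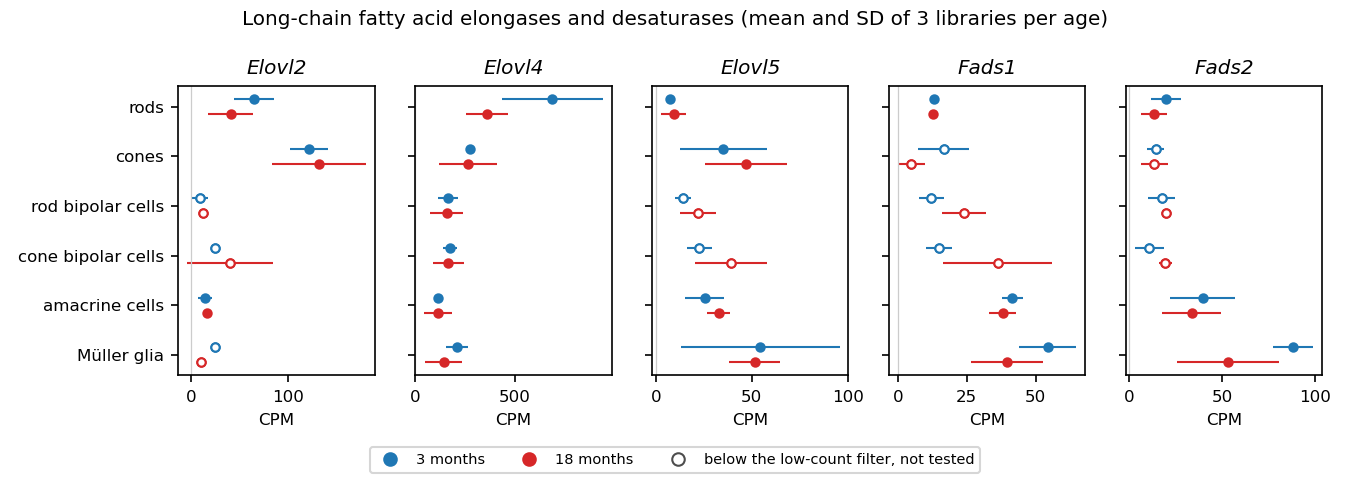
CPM of Elovl2, Elovl4, Elovl5, Fads1 and Fads2 in the 6 main classes, as mean and SD of 3 libraries per age, with open points for genes below the low-count filter (plain CPM) and filled points for tested genes (normalised CPM). Elovl4 in rods has the highest level, at 688 and 359 normalised CPM.

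Müller glia, the radial glia of the retina, were compared in the same way. With age as the only term, no gene passed in edgeR (0 of 7069, with 307 at an unadjusted p under 0.05), and DESeq2 called 22. The replicate number as a term gave 113 calls. With the release term 86 passed, 45 higher and 41 lower. The named gene that rose most was Csmd1, a large membrane protein of neurons (ENSMUSG00000060924, chromosome 8, 15892537 to 17535586), from 80.3 ± 16.9 to 302 ± 37.4 normalised CPM (SD, n = 3), a log2 change of 1.95 ± 0.30 (SE) with an adjusted p of 0.00146. Kcnip1, a Kv channel interacting protein, the neurotrophin receptor Ntrk2 and the GABA receptor subunit Gabrb1 rose as well, with Ano4, Ralyl, Kcnb2, Edil3, Dscam, Dgki, Fgf14 and Fam155a, at log2 changes of 1.11 to 1.82. The named genes that fell were mostly photoreceptor genes: Gnat1, rod transducin (1300 ± 241 to 557 ± 69.0), Reep6, Nxnl2, Drd4, Prcd, Rdh12, Pdc, Nr2e3, Cdhr1 and Rom1, with Atp5k of the ATP synthase.

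By class of highest mean CPM, 39 of the 41 lower calls in Müller glia were highest in rods and 0 of the 45 higher calls were highest in Müller glia. Of the rod phototransduction genes 13 of 28 passed with the release term, and adjusted over the list alone 20 passed in that fit and 11 with age alone. Of the mitochondrially encoded genes 8 of 13 passed with the release term, and adjusted over the list alone 12 passed in that fit and 9 with age alone. The count of 86 became 8, 17, 182 and 177 without 3-month replicates 2 and 3 and 18-month replicates 2 and 3, and 1 gene passed in the libraries of release 7.2.0 alone.

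In the other classes no gene passed with age as the only term in edgeR. At an unadjusted p under 0.05 there were 134 genes of 8267 in cones, 98 of 6641 in rod bipolar cells, 114 of 6480 in cone bipolar cells, 281 of 12507 in amacrine cells, 278 of 5435 in horizontal cells and 260 of 13628 in retinal ganglion cells. DESeq2 called 36 genes in horizontal cells, 35 of them higher, and 0 in the rest. With the release term 5 genes passed in horizontal cells and 4 in cone bipolar cells. The one that met the naming rule was AC149090.1, a gene on an unplaced scaffold, at 56.4 ± 25.8 and 258 ± 175 normalised CPM in horizontal cells (log2 change 2.12 ± 0.30, adjusted p = 0.03). The other calls in horizontal cells fell outside that rule and are named after their values were seen: Samsn1, Cdh11 and Zfp804b were higher (log2 changes of 3.72, 3.70 and 4.43) and mt-Nd3 was lower. The cone genes Arr3 (380 ± 217 to 99.9 ± 45.8) and Opn1mw (150 ± 93.0 to 21.7 ± 27.4) fell in cone bipolar cells, where they stood at 2.50% and 3.13% of their level in cones. The remaining calls there, likewise outside the rule, were AC149090.1, higher by 1.57 on the log2 scale, and AI847159, lower.

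The final comparison asked whether the age effect differed between rods and Müller glia. No gene passed (0 of 10580 in edgeR, with 491 at an unadjusted p under 0.05), and DESeq2 called Immp2l alone, whose log2 change was higher in rods by 2.24 (adjusted p = 0.024). The genes that passed in rods and not in Müller glia are therefore not shown to differ between them. The interaction test found 14% of simulated 4-fold differences, in counts without deviations shared by both classes of a library.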

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

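The fits with the Cell Ranger release, the libraries of release 7.2.0 alone, the mitochondrial limit of 15% and shares among named classes were chosen after the data had been examined, and the other settings before. None of the 120 values of named genes passed with age alone. Of 2359 values under another setting, 1852 kept direction and did not pass, 469 kept it and passed, and 38 changed sign. The settings include the fit with the release term, from which genes had been named, so the 469 do not add to the calls. For the 40 pairs of list and class, 551 of 642 kept both, 90 no longer passed and 1 changed sign. For shares, 134 of 154 kept direction. The counts of genes per class were 0 with age alone, and 117 of 162 stayed at 0. The count of list pairs was 35 to 44 under every other setting but became 0 with an estimated correlation. The nuclear-encoded oxidative phosphorylation list in rod bipolar cells had an adjusted p of 3.82e-15 to 0.76 with 1 library left out, the highest without 3-month replicate 2, and turned higher without 18-month replicate 1 (0.65). Unless said otherwise, the cause was not tested for any value below.

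Counts of genes, each 0 with age alone, were as follows. DESeq2 gave 11 in rods, 22 in Müller glia, 36 in horizontal cells and 1 for the difference between rods and Müller glia. Without the low-count filter they were 2 in rods, 56 in cones, 2 in rod bipolar, 7 in cone bipolar, 1 in amacrine and 232 in horizontal cells, 22 in Müller glia and 1 for the difference. The other clustering gave 251 in rods, a class that then held 49 and 68 instead of 433 and 1050 nuclei in the libraries of release 7.1.0, thinned sums 1 in rods and 3 for the difference, doublets kept 3 and the 15% limit 2 for the difference. With 1 library left out, the ranges were 0 to 2 in rods (2 without 3-month replicate 1), 0 to 9 in Müller glia and 0 to 171 in horizontal cells (both highest without 18-month replicate 1) and 0 to 5 for the difference (5 without 3-month replicate 1). The release term gave 1124 in rods, 86 in Müller glia, 4 in cone bipolar and 5 in horizontal cells. Release 7.2.0 alone, with 2 libraries per age, gave 1861 in rods (996 of the 1124 among them), 1 in Müller glia, 20 in cone bipolar cells, 218 in horizontal cells and 7 for the difference. When the release term was kept and 3-month replicate 2 left out, the counts were 17 in rods, 8 in Müller glia and 8 in cone bipolar cells. Without 3-month replicate 3 they were 9 in rods and 17 in Müller glia. Without 18-month replicate 2 they were 56 in rods, 13 in rod bipolar, 2 in cone bipolar and 2 in amacrine cells and 182 in Müller glia. Without 18-month replicate 3 they were 634 in rods, 70 in cones, 17 in rod bipolar, 2 in cone bipolar, 69 in amacrine, 26 in horizontal and 308 in retinal ganglion cells and 177 in Müller glia. These last 4 fits leave 1 library in 1 arm of release 7.2.0, and across them counts rose in some classes and fell in others.

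The replicate numbers were checked for pairing by the correlation across genes of deviations from the age means. It was 0.60, 0.51 and 0.11 for replicates 1 to 3 in rods and 0.59, 0.16 and 0.10 in Müller glia, and all pairs were over 0.1 in 2 of 8 classes, rods and retinal ganglion cells, so the numbers were not taken to pair the samples. Between 2 and 5 of 6 libraries per class correlated best with their own number. With the number as a block, 1137 genes passed in rods (979 shared with the release term), 113 in Müller glia and 2 in horizontal cells, and Elovl5 in rods changed sign, to 0.002. Its list count was 42.

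Fatty acid genes, none of which passed with age alone, changed sign in these fits, given as log2 changes. With release 7.2.0 alone they were 0.275 for Elovl4 in amacrine cells, 0.222 for Elovl4 in cones, and 0.112, 0.052 and 0.015 for Elovl5, Fads1 and Fads2 in rods. With the release term and without 18-month replicate 2 they were 0.107 and 0.192 for Elovl4 in amacrine and rod bipolar cells and 0.203 for Elovl5 in rods. Without 18-month replicate 3 they were -0.042 for Elovl2 in amacrine cells and 0.052 for Fads1 in rods, and without 3-month replicate 3 -0.265 for Elovl2 in amacrine cells. The other clustering gave 0.098 for Fads2 in rods, no low-count filter 0.094 for Elovl4 in rod bipolar cells and thinned sums -0.284 for Elovl2 in cones. The stricter limits on nuclei gave 0.231 for Elovl4 and 0.269 for Fads2 in amacrine cells. With age alone and 1 library left out, Elovl2 in cones ranged from -0.166 to 0.325 and Elovl2 in amacrine cells from -0.270 to 0.437. Elovl4 in amacrine cells ranged from -0.630 to 0.228, Elovl4 in cone bipolar cells from -0.424 to 0.138, Elovl4 in rod bipolar cells from -0.501 to 0.198 and Elovl4 in cones from -0.574 to 0.202. Elovl5 in rods ranged from -0.336 to 0.125, Elovl5 in cones from -0.156 to 1.155 and Elovl5 in Müller glia from -0.632 to 0.607. Fads1 in rods ranged from -0.108 to 0.070, Fads2 in rods from -0.540 to 0.065 and Fads2 in amacrine cells from -0.598 to 0.231.

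Differences in shares, in percentage points, changed sign as follows. The stricter limits gave 1.04 for the share of Müller glia, 6.36 for the share of amacrine cells, 2.13 for the share of cones and 3.34 for the share of rods. Among named classes, Müller glia were at 0.589 and amacrine cells at 9.92, and the share of horizontal cells kept its sign at -0.39, and the 15% limit gave 1.12 for amacrine cells. The other clustering, in which no cluster was named cone bipolar, gave 0 for that class and -0.649 for the share of rod bipolar cells. With 1 library left out, Müller glia ranged from -2.52 to 1.55, amacrine cells from -3.88 to 3.92, the share of cone bipolar cells from -1.56 to 0.158, cones from -4.5 to 0.0573 and the share of endothelial cells from -0.00309 to 0.0821. The share of retinal pigment epithelium, named at the main setting in 18-month replicate 3 alone, ranged from 0 to 0.391. Rod bipolar cells ranged from -0.0287 to 0.938 and rods from -15.5 to 0.0497. Clusters 33.1 and 33.2, unnamed for markers of several classes, had 9 and 8 of 12 pigment epithelium markers. They held 13 and 12 nuclei of 3-month replicate 3. The other clustering named 0.0306% of 3-month replicate 3 as pigment epithelium. The stricter limits left enough nuclei for amacrine, horizontal and retinal ganglion cells only, so they gave no gene count for the other classes or the difference, and the other clustering gave none for cone bipolar cells. Depth was low in places: cone bipolar sums reached down to 54570 UMIs, and Elovl2 in Müller glia rested on 20 and 14 UMIs.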

Other observations

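Rps29, a protein of the small ribosomal subunit, was lower at 18 months without overlap between the ages in all 8 tested classes, and mt-Cytb, cytochrome b, in 7. The photoreceptor genes Gnat1, Nrl and Reep6, with Atp5k and Rps28, were among those lower without overlap in 6 classes, and Frmd5, Immp2l, Kdm2a and Usp29 were higher in 6. Since all classes come from the same 6 libraries, no chance value is given for agreement across them. Within a class, chance gives 10% of genes without overlap for 3 against 3 libraries. The share was 12.9% in rods (1467 of 11382 genes), 10.3% in Müller glia, 9.35% in horizontal cells and 6.16% to 7.44% in the other 5 classes. Samsn1, a signalling adaptor chosen after its values were seen, stood at 6.69 ± 2.16 and 105 ± 37.0 plain CPM in horizontal cells (SD, n = 3; log2 change 3.71, adjusted p = 0.0559 with age alone and 0.00559 with the release term). In Müller glia Samsn1 stood at 80.4 ± 6.40 and 197 ± 21.2 plain CPM, with an adjusted p of 0.0233 with the release term, while in cone bipolar cells, where it was highest, it stood at 1290 ± 191 and 1280 ± 273. Of the 10 measured genes of interferon response and antigen presentation in Müller glia, 10 were higher at 18 months, and the list did not pass (adjusted p = 0.173).

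Of the tests that follow, matching on mitochondrial percent, the comparison within rod cluster 5 and the splits for the gene lists and for the rod and Müller glia difference were set out before their results were seen. The comparisons within each Cell Ranger release, the tests of free RNA and the splits for single genes were chosen after the results were seen.

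Cytosolic ribosome and respiratory chain transcripts were lower in 18-month rods, with median log2 changes of -1.11 and -1.01 with the release term. A batch difference between Cell Ranger releases is argued against as the whole source by the design, not by a test. Each age has 1 library of release 7.1.0 and 2 of release 7.2.0. The ribosomal median was -0.70 within release 7.1.0 and -1.20 within release 7.2.0. A batch difference that does not follow the release was not tested. A lower carry-over of cytoplasmic RNA with the 18-month nuclei stays open. In rods drawn to a like mitochondrial percent in every library, the ribosomal median was -0.79, which is 0.714 of the unmatched value (95% interval over genes 0.678 to 0.759), and the respiratory chain kept 0.733. Genes of the list are not independent replicates, and that interval does not cover the spread between libraries or the random draw of rods. The median of the mitochondrially encoded genes, whose share was matched, went from -0.85 to -0.11, and the count of genes that passed went from 1124 to 315 in 59 to 1428 rods per library. That ratio lies between the bound set for this source, under 0.5, and the bound set against it, 0.75, and an effect of age on the rods themselves was not tested apart from it. All these rods had passed the mitochondrial limit of 5%, which removed 9.36% to 41.9% of barcodes per 3-month library and 1.12% to 9.16% per 18-month library.

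Of the 86 genes that passed in Müller glia with the release term, 39 of the 41 lower ones were highest in rods, against 27.9% of the 6983 genes not called, and 44 of the 45 higher ones in a class of inner retinal neurons, against 39.1%. This tally was made after the calls were seen and was not tested, and with age alone 0 genes passed and in release 7.2.0 alone 1. Free RNA from other cells may contribute: 33.7% of the 86 genes called with the release term had a mean CPM below 0.2 of the highest class, against 3.41% of the 6983 genes not called (Fisher's exact test across genes, two-sided, p = 1.21e-20; genes are not independent replicates). The share is above that of the other genes and under the 50% set for this source, so free RNA cannot be told apart from an age effect in Müller glia, which was not tested.

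Dpp10 was higher in 18-month rods. Free RNA that reaches all classes alike is argued against in 2 of the 3 18-month libraries. There plain CPM in rods was 28.2 and 27.4 times that in horizontal cells. The ratio was 1.14 in replicate 3, where free RNA stays open. Horizontal cells were chosen for this comparison after the results were seen. Dpp10 was also higher without overlap in cones (17.6 to 34.7 plain CPM at 3 months and 50.1 to 197 at 18 months). The same held in cone bipolar cells (26.5 to 67.0 and 81.6 to 495), and the ages overlapped in the remaining classes. Different rod clusters at the 2 ages are argued against as the whole source, since the fold within rod cluster 5 was 9.51 without overlap, although 3-month replicate 1 has 1 UMI of Dpp10 there. In rod cluster 2 the ages overlapped, at 173, 17.5 and 21.3 plain CPM in 3-month replicates 1 to 3 and 0, 56.7 and 0 in 18-month replicates 1 to 3. These rested on 7, 35 and 18 UMIs of Dpp10 and on 0, 6 and 0. In 18-month replicate 2 cluster 5 stood at 487, so a part from the mix of rod clusters stays open. A batch difference between releases is argued against as the source by the design, since both releases occur at both ages. A batch difference that does not follow the release was not tested. Within release 7.2.0 alone plain CPM went from 31.0 and 27.3 to 481 and 482, a fold of 16.5. The fold was 5.47 within release 7.1.0, with 1 library per age. Since Dpp10 had been picked from the fit with the release term, these folds do not add to its call. An effect of age on the rods themselves stays open and was not tested apart from these.

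The 6 libraries make 10 splits into 3 and 3, too few for a share of splits under 0.05. With age alone the real count was 0 genes in each class. All 10 splits reach 0 whatever the data, so this comparison cannot decide. The highest other split had 1996 genes in rods, 1547 in cones, 1125 in cone bipolar cells, 772 in rod bipolar cells, 36 in retinal ganglion cells, 1 in Müller glia and 0 in amacrine and horizontal cells. In the first 5 of these classes that split set 3-month replicate 1 and 18-month replicates 1 and 3, with both libraries of release 7.1.0 among them, against the rest, which points to a structure of the samples that the ages do not follow. With the release term, 1 of 10 splits, the real one, reached the 1124 genes in rods and the 86 in Müller glia, with 0 as the highest other, and the 4 in cone bipolar cells, with 2. In horizontal cells 3 of 10 splits reached the 5 genes, with 128 as the highest other. In the classes with 0 genes all 10 reach it whatever the data, with up to 228 in cones, 425 in rod bipolar cells, 264 in amacrine cells and 476 in retinal ganglion cells. Like the ages, 6 of the 10 splits part the 2 libraries of release 7.1.0, while the other 4 put both in 1 arm and overlap with the release term. Among the 6 the highest other count with the release term was 0 in 7 classes and 33 in horizontal cells. The count of 40 list and class pairs was reached by 1 of 10 splits, with 34 as the highest other. For the rod and Müller glia difference all 10 reach 0 whatever the data, with 4 as the highest other.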
